A study of Arabidopsis thaliana with 3 samples.

How the data were processed

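Total RNA from wild-type and agamous inflorescences of Arabidopsis thaliana was compared on 3 cDNA arrays with 2 channels each, per the labels, which name wild type as the source of channel 1 and agamous as the source of channel 2. The authors' deposited values are 1 log2 ratio per feature and array, and per the labels they were preprocessed and normalized as in a publication of the group. The steps of that processing, the scanner, the dyes, whether dyes were swapped, whether spots were averaged and whether the wild-type RNA was a single pool are not given in the sources used here. The scale was worked out from the deposited values. Multiplied by the natural logarithm of 2, between 98.8% and 98.9% of the values of each array lie on a grid of 0.0001 within a tolerance of 1.2e-06, where chance would give 2.4%. Natural log ratios kept to 4 decimals and rescaled to base 2 have this property, so the values were read as log2 ratios. Every fold given rests on that reading. How the authors centred the arrays and which channel is the numerator stay unknown; the median log2 ratio was -0.19, -0.16 and -0.11 in replicates 1, 2 and 3, and the main peak of each array lay at -0.03, -0.03 and 0.05.

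The table holds 9368 features from 114 plates, with 28 to 94 features per 96-well plate. Feature names give a plate and a well. A match of the names to the symbols, locus tags, synonyms and accessions of the given reference table (assembly TAIR10.1) found 0 genes. The 10 gene lists that had been fixed (331 loci, covering floral regulators, anther, pollen, carpel, photosynthesis, cell cycle, cuticle, flavonoid, jasmonate and reference genes) were therefore not tested, and neither was any list of other cell types. No 2 arrays held identical values. Nothing in the labels says whether the arrays came from separate plants, so p-values measure the spread between these arrays, which may be technical. They leave out the spread of the wild type if its RNA was 1 pool. No intensity, background or flag was used, so no filter on dim spots was possible, and the number of arrays limits the precision.

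Each feature's mean log2 ratio was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, eBayes), two-sided, over all 9368 features, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual degrees of freedom per feature and a prior of 4.54 degrees of freedom. The design planned the mean of a locus's features, which without loci is each feature by itself. The rule for named genes took the 10 largest absolute means on each side among features past the threshold with the same sign on all arrays and a gene locus; with no loci, the first 2 on each side are named by plate and well.

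The fit was tested on simulated data for this comparison with all 9368 features, of which 200 were changed and the spread was drawn from the prior of the real fit. It recovered 4% of the 50 features changed by 0.5 on the log2 scale, 76% of those changed by 1, and 100% of those changed by 2 and of those changed by 4. Among its calls, 3.45% were unchanged features. Far fewer features were changed in the simulation than the 4238 called in the data. Its spread also did not depend on the size of the change, as it did in the data. These shares therefore do not give the power or the false calls of the real fit.

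Alternatives fixed before the data were examined were centring on the median, centring with scaling by the median absolute deviation, quantile normalization between arrays, eBayes with trend and robust, array weights, leaving out the 10% of features with the highest SD, a threshold of 0.01, a minimum mean of 1 on the log2 scale, and leaving out each array. Centring on the mode and splits by plate were added after the data were seen. Plate shares, density peaks, neighbouring wells and permutation tests were computed with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3. Second peaks were sought with Gaussian kernels of bandwidths 0.2, 0.3 and 0.4 on the log2 scale, and the main peak of each array and of each set of plates, used for centring and offsets, with a bandwidth of 0.1. Intervals over plates come from 1000 bootstrap samples of plates.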

Results

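Gene expression was compared between inflorescences of wild-type Arabidopsis thaliana and of the agamous mutant, named for AGAMOUS, the MADS-box transcription factor gene that specifies stamens and carpels and ends the growth of the floral meristem. In flowers without its function petals stand in place of stamens, and further flowers form in place of the carpels. Total RNA of the 2 genotypes was hybridised together on 3 spotted cDNA arrays, with wild type in the first channel and agamous in the second, per the labels. All 3 arrays form 1 group and are called replicates 1, 2 and 3. Each array gave a log2 ratio for the same 9368 features, with 0 missing values. A feature is known here only by the plate and well of its clone, such as GP002D3 for plate 002, well D3, and 0 of the features could be matched to a gene, so no gene, position in the genome or pathway is named. AGAMOUS itself was therefore not analysed here. The labels do not say which channel is the numerator of the ratio, so results are given as the negative and the positive side, with the signs as deposited. No spot intensities or backgrounds were used, and the number of arrays limits the precision.

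The first question was for how many features the signals of the 2 kinds of inflorescence differed. More than 1 feature may stand for the same transcript, so these are not counts of transcripts. The dyes are not given, so a dye bias repeated on all arrays would also be counted. Of the 9368 features, 4238 (45.2%) had a mean log2 ratio different from 0 at an adjusted p under 0.05 in limma's moderated test with Benjamini-Hochberg adjustment (n = 3 arrays). On the negative side lay 3064 of these (32.7% of all features), and on the positive side 1174 (12.5% of all features). All 4238 had the same sign on all 3 arrays, which is not separate support, since the test favours features whose arrays agree. In all, 6664 features (71.1%) had the same sign on all 3 arrays, where independent signs at each array's own share of negative values would give 28.4%. The arrays' medians were -0.19, -0.16 and -0.11 in replicates 1, 2 and 3. With each array centred on its median, the same test called 2754 features on the negative side and 1778 on the positive side. The positive share of the calls was then 39.2% instead of 27.7%.

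The differences on the negative side were larger. The called features on the negative side had a median mean log2 ratio of -2.57, a 5.93-fold difference between the channels, with quartiles of -3.71 and -1.07. On the positive side the median was 0.74, a 1.67-fold difference, with quartiles of 0.56 and 0.93. At a mean of at least 2-fold, 2359 called features lay on the negative side and 221 on the positive side. At least 4-fold differences were found for 1787 called features on the negative side and for 0 on the positive side. On the negative side, 1288 features passed 8-fold and 568 passed 16-fold. Among called features below 2-fold the order was turned, with 705 on the negative side and 953 on the positive side.

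**Figure D1:**
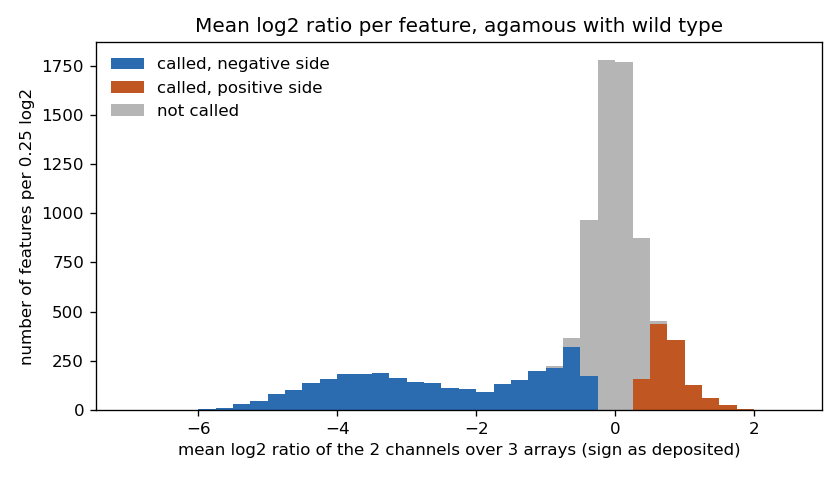
Histogram of the mean log2 ratio over the 3 arrays for 9368 features (x axis, log2, sign as deposited; y axis, number of features per 0.25 log2). Colours separate the 3064 features called on the negative side, the 1174 called on the positive side and the rest; a second, lower peak lies near -3.49 on the negative side.

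The ratios did not tail off evenly on the negative side but formed a second peak. With a kernel bandwidth of 0.3 on the log2 scale, the mean ratios had a main peak at -0.01 and a second at -3.49, an 11.2-fold difference, separated by a minimum at -2.07. Below that minimum lay 1757 features, 18.8% of all. Most of these were clones of plates 000 to 118, of which 1687 of 7098 (23.8%) lay below -2.07, against 70 of 2270 (3.08%) on plates 119 to 147. The second peak of the plates up to 118 was at -3.49, while the few low features of the other plates gave no single second peak at this bandwidth. Each array on its own gave the same 2 peaks, with the second at -3.51 ± 0.38 (SD, n = 3) and 18.7% ± 0.40 of the features below the minimum (SD, n = 3). The second peak was at -3.90 in replicate 1, -3.14 in replicate 2 and -3.48 in replicate 3. Each array's share was counted below its own minimum, at -2.23, -2.01 and -2 in replicates 1, 2 and 3. No test was run on the number of peaks.

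The most extreme features on the negative side had mean log2 ratios between -6.47 and -5.64 over the 10 lowest, with adjusted p of 1.8e-05 or less in limma's test. GP008F9 had the lowest mean, -6.47 with a moderated standard error of 0.41, an 88.9-fold difference (adjusted p = 1.4e-05, limma). Its values were -7.22, -5.07 and -7.13 in replicates 1, 2 and 3. GP105A1 had a mean of -6.16 with a standard error of 0.35, a 71.5-fold difference. On the positive side, the 10 highest means lay between 1.65 and 1.99. GP002D3 had the highest, 1.99 with a standard error of 0.17, a 3.99-fold difference (adjusted p = 7.7e-05, limma). Its values were 2.19, 2.23 and 1.57 in the 3 replicates. GP002D12 followed with a mean of 1.95 and a standard error of 0.17. Of the 10 highest features, 4 came from row D of plate 002, with means between 1.88 and 1.99. These features have no gene locus here and so lie outside the rule that was fixed for named genes; they are its first 2 on each side once the locus is not asked for, chosen after their values were seen.

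The values of the 3 arrays ran in the same direction. Across all features, which are not independent replicates, Pearson's r was 0.970 between replicates 1 and 2, 0.951 between 1 and 3, and 0.956 between 2 and 3. Over the 6783 features with a mean within 1 of 0, r was lower, at 0.767, 0.559 and 0.627 for the same pairs. The SD of a feature over the 3 arrays had a median of 0.24 on the log2 scale over all features. It was 0.20 for features with a mean between -1 and 1, and 0.35 for means above 1. On the negative side it was 0.32 for means between -3 and -1, and 0.49 for means below -3. The share of features at or below -1 was 26.8%, 24.98% and 24.6% in replicates 1, 2 and 3, a mean of 25.4% ± 1.18 (SD, n = 3). The share at or above 1 was 5.59%, 3.68% and 0.811%, a mean of 3.36% ± 2.41 (SD, n = 3). This share varied more between arrays than the share at or below -1. The median SD of single features, 0.35 above 1, lay between 0.32 and 0.49 on the negative side. The means differed in size between these sets, so the SDs cannot tell whether the arrays agreed equally well on both sides. Without replicate 2 the positive calls fell to 603 and without replicate 1 to 754, while the negative calls were 2638 and 2789.

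Features on which the arrays disagreed were picked by 2 rules set after the values were seen, so their medians follow in part from the rules. In 33 features from 28 plates, replicate 1 was at or below -2 while replicate 2 lay above 0.3 times the value of replicate 1. Their medians were -3.05, -0.61 and -1.59 in replicates 1, 2 and 3, and 30 of them were called on the mean. With replicates 1 and 2 exchanged, the same rule took 0 features. Replicate 2 had a narrower range of values (SD over features 1.402, against 1.69 in replicate 1). Whether that accounts for the 0 was not tested. In another 57 features from 42 plates, replicate 1 was at or below -0.8 and replicate 3 at or above 0.5, with medians of -1.38, -0.33 and 0.81 in replicates 1, 2 and 3. The rule with replicates 1 and 3 exchanged took 1 feature.

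**Figure D2:**
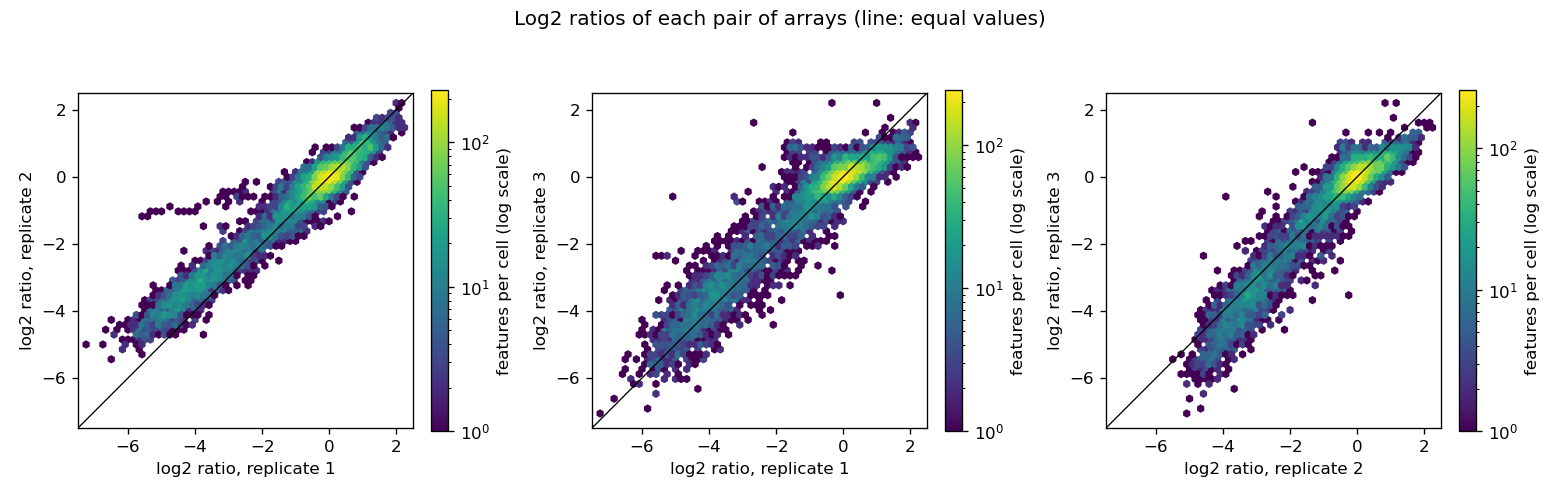
Log2 ratio of each feature on 1 array (x axis) against another (y axis) for the 3 pairs of arrays; colour gives the number of features per hexagon on a log scale and the line marks equal values. Pearson's r across features is 0.970, 0.951 and 0.956, and a thin band of features with low values in replicate 1 and higher values in replicate 2 lies above the main cloud in the left panel.

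The share of features with large negative ratios depended on the plate of the clone. On the 85 plates numbered 000 to 118, 2221 of 7098 features (31.3%) had a mean log2 ratio at or below -1. On the 29 plates numbered 119 to 147, the count was 143 of 2270 features (6.30%). Taken array by array, the shares were 31.5% ± 1.28 and 6.49% ± 0.87 (SD, n = 3 arrays); this SD is that of repeated measurement of the same clones, not the spread between plates. The share on single plates ranged from 1.43% to 46.7% before the break and from 1.23% to 12.5% after it, so the ranges overlapped. Among the earlier plates the share was also low on plates 000 to 006 (47 of 401 features, 11.7%), 032 to 035 (31 of 246, 12.6%) and 042 (7 of 79, 8.86%), which were singled out after the shares were seen; the other 73 earlier plates had 33.5%. Large positive ratios, at or above 1, were found for 2.86% of the features on the lower-numbered plates and for 0.793% on the others. Calls in the test over all features made up 52.8% and 21.5% of the features of the 2 sets of plates. The position of the break was found from the data as the best single split along the plate numbers. In a permutation test that shuffled the plates and searched for the best split again, p was 1e-05, the smallest that 100000 shuffles can give. Shuffling treats the plates as exchangeable, but low shares also came in runs of earlier plates. The test therefore shows that the share depended on plate order, and cannot tell whether there was a single break.

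**Figure D3:**
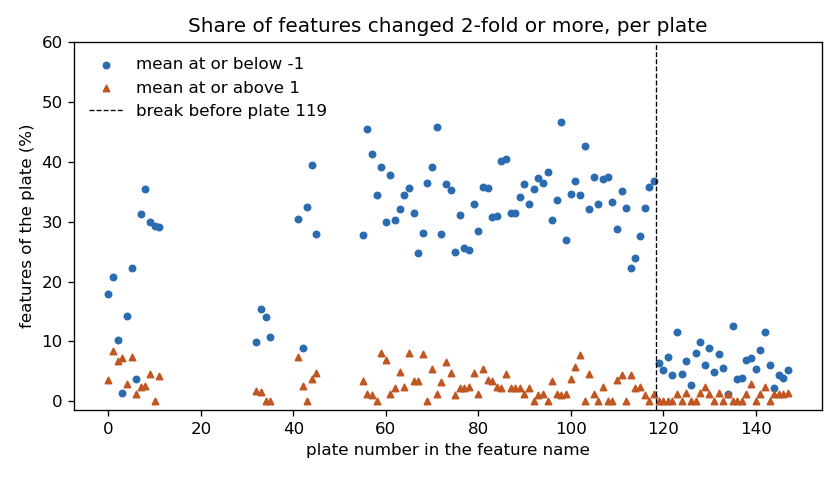
Percentage of each plate's features with a mean log2 ratio at or below -1 (circles) and at or above 1 (triangles), against the plate number in the feature name, for 114 plates. Plates 119 to 147, right of the dashed line, have shares at or below -1 of 12.5% or less.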

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

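The total count of calls stayed within 1.5 times of 4238 under all alternatives fixed beforehand except the minimum mean of 1, which kept 2580 (221 on the positive side, 8.57% of the calls). No call common to the reported fit and another setting changed sign. The negative count of 3064 stayed within 1.5 times under all those alternatives; leaving out 1 array gave 2638 to 2908. The positive count of 1174 was less stable: it was 1778 with each array centred on its median, 615 at an adjusted p under 0.01, and 603 to 1063 with 1 array left out. The positive share of the calls, 27.7%, moved to 39.2% with median centring, 38.8% with scaling by the median absolute deviation as well, 29.3% with quantile normalization, 30.9% with trend and robust, 34.9% without the most variable features, 19.2% at an adjusted p under 0.01, and 18.6% to 26.8% with 1 array left out. Apart from a common shift of all arrays, negative calls outnumbered positive calls in every setting given here. Shifting all arrays by 0.28 on the log2 scale, tried after seeing the data, gave 2607 negative and 2679 positive calls. Among settings chosen after seeing the data, centring each array on its mode left 3040 negative and 1109 positive calls and leaving out plates 000 to 006 left 2988 and 1102. Plates 119 to 147 alone gave 567 calls, 368 negative and 199 positive (35.1% positive); plates 000 to 118 alone gave 3714. These are 24.98% and 52.3% of the features tested. The cause of these shifts was not tested. The 4 named features kept their sign and an adjusted p (limma) of at most 0.00164 in all 38 values computed; GP008F9 and GP105A1 were themselves removed with the most variable features. The correlations between arrays cannot change with centring. Each feature on its own, the median of a locus's features and a minimum of 2 arrays equal the reported fit here and were not run, and the gene list alternatives were not run because no list could be matched. With 3 arrays of 1 group, the 4 sign patterns are too few for a share under 0.05: the arrays as deposited gave 4238 calls, 1 of the 4 patterns gave as many, and the other 3 gave 0 at most (25 features at most at an unadjusted p under 0.05, against 4867). No paired analysis was possible because there is 1 group. Spot signal over background was not used, so its limits are unknown.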

Other observations

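Except for the test of the ratio's direction with the fixed organ lists, the tests in this part were chosen after the data had been seen.

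On the positive side, replicate 3 had smaller ratios than both other arrays. Among features at or below -3 in replicate 1 or 2, its ratios lay between those of replicates 2 and 1. Its share of features at or below -1 was the lowest, 24.6% against 26.8% in replicate 1 and 24.98% in replicate 2. Among the 524 features at or above 1 in replicate 1, the median was 1.03 in replicate 2 and 0.62 in replicate 3. Among the 1450 features at or below -3 in replicate 1, it was -3.39 in replicate 2 and -3.80 in replicate 3. Choosing on replicate 2 gave medians of 1.22 and 0.71 in replicates 1 and 3 for the 345 features at or above 1, and -4.40 and -4.10 for the 1072 features at or below -3.

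The first pattern is the excess of the negative side, with 3064 calls against 1174 and a second peak near -3.49. Arrays centred off the bulk of the features would give an excess of calls, but equal calls on both sides needed all arrays shifted by 0.28 on the log2 scale, while their main peaks lay at -0.0023 ± 0.045 (mean, SD, n = 3, bandwidth 0.1) or -0.01 ± 0.035 (bandwidth 0.3). That argues against arrays centred off their main peaks. It cannot show that features without a difference lie at 0, since the authors' centring is unknown. Median centring narrowed the calls to 2754 and 1778. After the shift of 0.28, 1666 features still had a mean of at least 4-fold on the negative side and 6 on the positive side. A biological hypothesis is that the negative side holds transcripts of organs that agamous flowers lack, the stamens and carpels, in which case the ratio would be agamous over wild type. The tests of this hypothesis and of the opposite direction of the ratio both need named genes, and 0 features could be matched to the fixed organ lists, so neither could be decided; a dye bias of single features also stays open, since the dyes are not given.

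The second pattern is the lower share of large negative ratios on plates 119 to 147, 6.30% against 31.3%; 12 earlier plates also had a low share, 11.7% together. A plate-wide offset of the ratios would need a shift of about 3.16 on the log2 scale, but the main peak after the break differed from that before it by -0.01 (95% bootstrap interval over plates -0.08 to 0.05). A compression of all ratios on these plates would scale every percentile alike, but the 10th percentile was 0.156 times that of the other plates (0.137 to 0.183) and the 1st percentile 0.806 times (0.743 to 0.850). The 90th percentile was 0.576 times that of the other plates (0.515 to 0.654). These values argue against an offset alone and against a compression by a single common factor alone. A compression together with other differences was not tested. Other technical causes were not tested either, and no spot intensities were used. That the later plates hold a different collection of clones, with fewer transcripts that differ between these inflorescences, was not tested and stays open, and no biological explanation was tested.

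The third pattern is that neighbouring wells on the lowest-numbered plates had like ratios. On plates 000 to 006, 23 of 291 pairs of next wells in a row differed by less than 0.2 over the 3 arrays (root mean square, log2) with both means at least 0.5 from 0, where shuffling wells within plates gave 2.79 on average (95% of shuffles 0 to 6; permutation p = 0.001, the smallest that 1000 shuffles can give), an 8.25-fold excess. A smooth trend of the ratios across the plate would do the same down the columns, where the count was 1 of 256 pairs, 0.437 times the shuffled mean, and on plates 007 and above the row count was 35 against 39.7 shuffled. The excess is consistent with the same cDNA in neighbouring wells, while carry-over between wells stays open. In row D of plate 002, wells D2, D3, D11 and D12 had means of 1.88, 1.99, 1.89 and 1.95 while the highest mean among the measured wells between D3 and D11 was 0.33, so these 4 of the 10 highest positive features may stand for fewer transcripts.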
